A study of Mus musculus with 2 samples.

How the data were processed

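Single-cell RNA sequencing was done on embryoid bodies, the aggregates that embryonic stem cells form when they begin to differentiate, made from J1 mouse embryonic stem cells, a male line. The embryoid bodies had received DMSO, the solvent control, or dTAG13 for 2 days before trypsin dissociation. dTAG13 is a small molecule that brings proteins fused to the FKBP12(F36V) tag to an E3 ubiquitin ligase, so that they are degraded. The labels do not say which protein carries the tag; the series title names Tex10. There was 1 library per group, so no difference between the groups has a replicate check, and no test, p-value or standard error was computed from cells.

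The deposited matrices hold whole-number UMI counts (counts of distinct tagged transcripts) per gene and cell barcode, made with Cell Ranger 8.0.1 per the file headers, from 10x Chromium 3′ libraries per the labels' protocols. The submitters' processing notes also name Seurat 5.0.1 and R 4.3.2, with no role given, and the genome build mm10. How barcodes were filtered before deposit is not given in the sources used here; the barcode with the fewest UMIs held 501 in the DMSO matrix and 502 in the dTAG13 matrix. Both matrices list the same 33696 gene identifiers, of which 1735 (5.15%) are absent from GENCODE M21, a release for mm10. The annotation and build behind the counts are therefore not settled, and no coordinates are given. Gene symbols were taken from the deposited files; 26 symbols have 2 identifiers, Aldoa and Ddit3 among them, and their counts were summed. Counting of reads from near-identical gene copies is not described in the sources used here, so values of histone, Rhox and Zscan4 family members are uncertain as single-gene values.

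Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet (scanpy 1.11.5, expected doublet rate 6%, automatic threshold) called 0 doublets in each library. A caller that marks under 0.5% of cells was taken, by a rule set before the data were examined, not to have worked, and nothing was removed as a doublet, so doublets remain among the cells. UMIs were summed over the kept cells of each library, divided by the library's total and given as CPM, the usual scaling of counts to a common total. Ratios are dTAG13 over DMSO. CPM has exact Poisson intervals, ratios have exact conditional binomial intervals and shares of cells have exact (Clopper-Pearson) binomial intervals, all at 95% and all covering counting error only.

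Gene lists were fixed before the data were examined: cell type markers (naive, shared and formative pluripotency, primitive streak, nascent mesoderm, definitive and extraembryonic endoderm, trophoblast, 2-cell-like, germ cell, neural ectoderm, fibroblast feeder), the Tex10 complex and rixosome, ribosome biogenesis, p53 targets, integrated stress response, dissociation and immediate-early genes, heat shock, glycolysis and hypoxia, cholesterol synthesis, Wnt, FGF-ERK, Nodal and BMP targets, DNA methylation enzymes, imprinted genes, polycomb, apoptosis, S phase, G2 and M phase, lysosome and autophagy, epithelial, mesenchymal, ribosomal proteins, the mitochondrial genome and the nuclear respiratory chain. For each list the median log2 ratio was taken over members with at least 5 CPM in 1 or both libraries. Its percentile among 10000 random lists of the same size, drawn from genes within 50 ranks of each member's mean CPM, describes these libraries and is no test. The counting interval of a list median came from 200 Poisson draws around the summed UMIs.

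Genes named in the text follow a rule fixed before the data were examined. Among genes with at least 20 CPM in 1 or both libraries and a UMI in at least 5% of the kept cells of the library where they were higher, leaving out predicted, ribosomal protein and mitochondrial genes, the 15 highest and the 15 lowest ratios were taken. From each list, up to 4 members with the largest absolute log2 ratio were taken among those with at least 10 CPM. Tex10, its complex, Pou5f1, Sox2 and Nanog were always named. Within clusters the 5 highest and 5 lowest ratios were taken by the same limits, and clusters are described by their leading genes. Genes outside the rule are marked as chosen after their values were seen. Not every gene that the rule selects is described here.

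For clustering, the kept cells of both libraries were put together without integration (2000 variable genes, 30 principal components, 15 nearest neighbours, leidenalg 0.10.2 at resolution 1). A cluster was named for a cell type only from the fixed markers, when that type had more markers than any other among the 10 leading genes and at least 3 markers at 10 CPM or more and at least 2 times their level in the other cells. For the trophoblast name, a limit set after the data were seen also required summed shared-pluripotency CPM of at most 0.5 of that in the other cells. Values within a cluster were planned for clusters with at least 200 cells from each library and are also given for those with at least 50. For values per cell, each cell was thinned at random to 3900 UMIs, and shallower cells were left out (1755 DMSO cells and 773 dTAG13 cells). A bound on free RNA came from the Zscan4 UMIs of cells outside the 2-cell-like cluster over the Zscan4 level of the whole library, added after the data were seen. Cell cycle phases were called with scanpy from the S phase and G2 and M phase lists.

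The ratio, its interval and the list percentile were tested on simulated library sums for the comparison of dTAG13 with DMSO. The simulation covered 8168 genes, of which 200 were changed. Sums were drawn from the Poisson model that the intervals assume, with no simulated cells. The results below thus check the calculation and not the variation between cells. Genes raised 1.5-fold came back at a median of 1.51 and those lowered to 0.5 at a median of 0.503. The intervals held the true ratio for 95.4% of genes, and 5.5% of 200 unchanged lists fell outside the central 95% of random lists. Alternatives covered the cell filter (all deposited barcodes, at least 1000 genes, at most 5% mitochondrial UMIs), doublets, scaling by the median of ratios, each cell weighted equally, the minimum CPM, clustering resolution (0.5 and 2), the genes used to cluster, and depth. Others were added after the data were seen: removal of the 8% of cells with the highest doublet scores, p53 members left out of other lists, single phases, Dppa5a left out, thinning before summing, and clustering without the genes that define the named clusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were used.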

Results

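Single-cell transcriptomes were collected from J1 mouse embryoid bodies after 2 days with DMSO or dTAG13, with 1 library per group. The DMSO matrix held 17958 barcodes and 117260846 UMIs, and the dTAG13 matrix held 11644 barcodes and 91850185 UMIs. After filtering, 17878 and 11588 cells remained, with 117189816 and 91808969 UMIs. Kept cells had a median of 6014 UMIs and 1966 genes in the DMSO library and of 7072.5 UMIs and 2251 genes in the dTAG13 library, and median mitochondrial shares of 2.48% and 1.97%. The dTAG13 library was thus deeper per cell. As each group is 1 library, every difference below is between these libraries and has no replicate check, and all intervals are 95% intervals that cover counting error only.

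The title of the series names Tex10 (ENSMUSG00000028345), a subunit of a nuclear complex with Pelp1, Wdr18 and Senp3 that works in ribosome maturation. Its mRNA was present in both libraries, at 81.3 CPM with DMSO and 64.7 CPM with dTAG13 (9531 UMIs, interval 9341 to 9724, and 5936 UMIs, interval 5786 to 6089), a ratio of 0.795 (0.770 to 0.821). dTAG13 acts on protein, so the mRNA level does not check the labels or the loss of a protein. Transcripts of 3 partners were also lower in the dTAG13 library: Pelp1 at 81.2 and 58.0 CPM, Wdr18 at 205 and 157 CPM, and Senp3 at 31.5 and 22.9 CPM in the DMSO and dTAG13 libraries. The rixosome enzymes Las1l and Mdn1 had ratios of 1.05 and 1.07, and Nol9 was at 47.3 and 56.8 CPM. The median log2 ratio of these 7 genes was -0.33, at percentile 0.965 of random lists. This median is the value of Tex10 itself, and 3 of the 7 had a ratio above 1, so it does not show a decrease across the complex. A Tex10 UMI was found in 39.5% (38.8 to 40.2) of DMSO cells and 38.4% (37.5 to 39.3) of dTAG13 cells, and after thinning to 3900 UMIs in 26.8% of 16123 and 22.8% of 10815 cells. No cell type that lacks Tex10 was defined here, so the share of cells that free RNA alone would give was not measured directly. Zscan4 UMIs outside the 2-cell-like cluster gave an upper bound on free RNA, if it has the make-up of the whole library. This bound was estimated at 4.62% (2.82 to 7.13) of DMSO and 4.98% (3.62 to 6.69) of dTAG13 UMIs. With counting error it reaches 7.13% and 6.69%.

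The design compares dTAG13 with DMSO. Targets of p53, the transcription factor that responds to DNA damage and to faults in ribosome assembly, were higher in the dTAG13 library. Mdm2 (ENSMUSG00000020184), the ubiquitin ligase that limits p53, was at 45.3 CPM with DMSO and 364 CPM with dTAG13, a ratio of 8.04 (7.81 to 8.27). The antiproliferative gene Btg2 (ENSMUSG00000020423) had a ratio of 8.01 (7.62 to 8.43), the kinase gene Plk2 (ENSMUSG00000021701) was at 20.3 and 141 CPM, and Perp (ENSMUSG00000019851), a membrane protein gene tied to apoptosis, was at 29.1 and 194 CPM. Of 31 measured members of the p53 list, 27 were at least 1.5-fold higher in the dTAG13 library and 0 were at least 1.5-fold lower. The list's median log2 ratio was 1.44 (counting interval 1.38 to 1.54), at percentile 100 of random lists. Chosen after its values were seen, Trp53 itself was at 460 and 456 CPM, a ratio of 0.991, and the cell cycle inhibitor Cdkn1a was at 66.9 and 232 CPM.

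**Figure D1:**
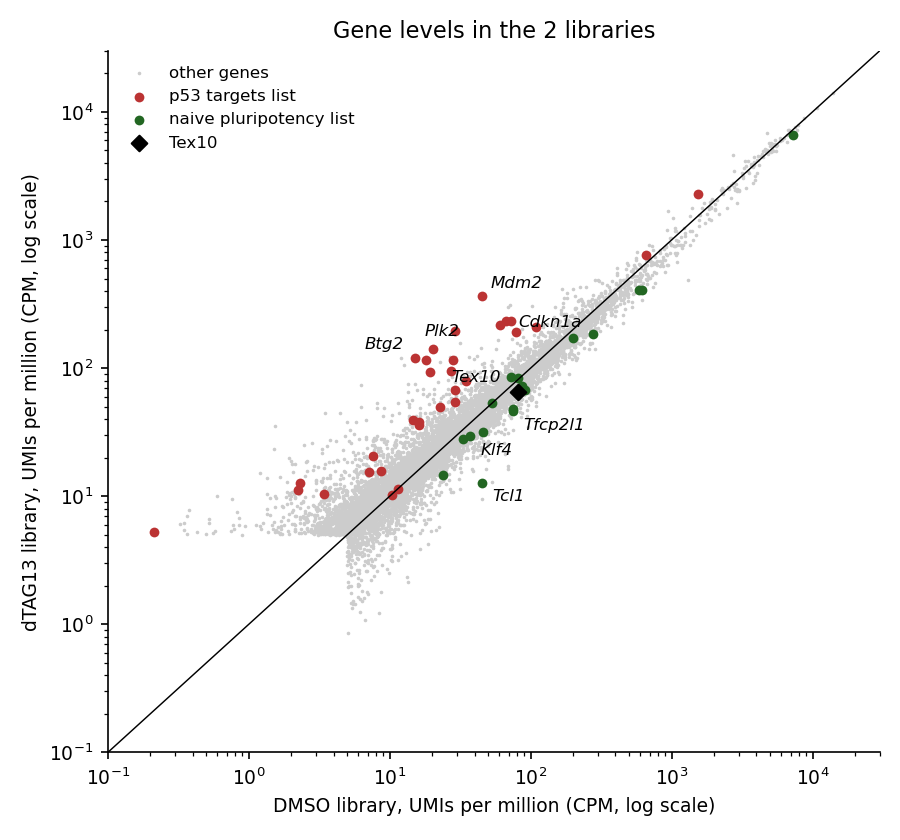
Level of each gene in the DMSO library (x axis, CPM, log scale) against the dTAG13 library (y axis, CPM, log scale), for genes with a UMI in both and at least 5 CPM in 1 or both, with the line of equal levels. Red points are the p53 target list, which lies above the line at a median log2 ratio of 1.44; green points are the naive pluripotency list, at a median of -0.43; the diamond is Tex10, at 81.3 and 64.7 CPM.

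Most dTAG13 barcodes held more p53 target UMIs than most DMSO barcodes, of which free RNA of the library may hold a part. At 3900 UMIs per cell, the list had a median of 11 UMIs in DMSO cells and 22 in dTAG13 cells (18 and 41 without thinning). Without Rps27l and Bax, which give most of the list's UMIs in DMSO cells, the medians were 3 and 11 (4 and 20 without thinning). Of the dTAG13 cells, 75.2% (74.4 to 76.0) lay above the 90th percentile of DMSO cells by this count, against 6.66% (6.28 to 7.06) of DMSO cells. The list was also higher in each phase taken alone, at median log2 ratios of 1.59 in cells called G1, 1.15 in S and 1.40 in G2 and M. The G1 value rests on 98 DMSO cells and sets unlike cells side by side, as 1365 of 1428 dTAG13 cells called G1 but only 14 of these DMSO cells lay in the keratin cluster described below.

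**Figure D2:**
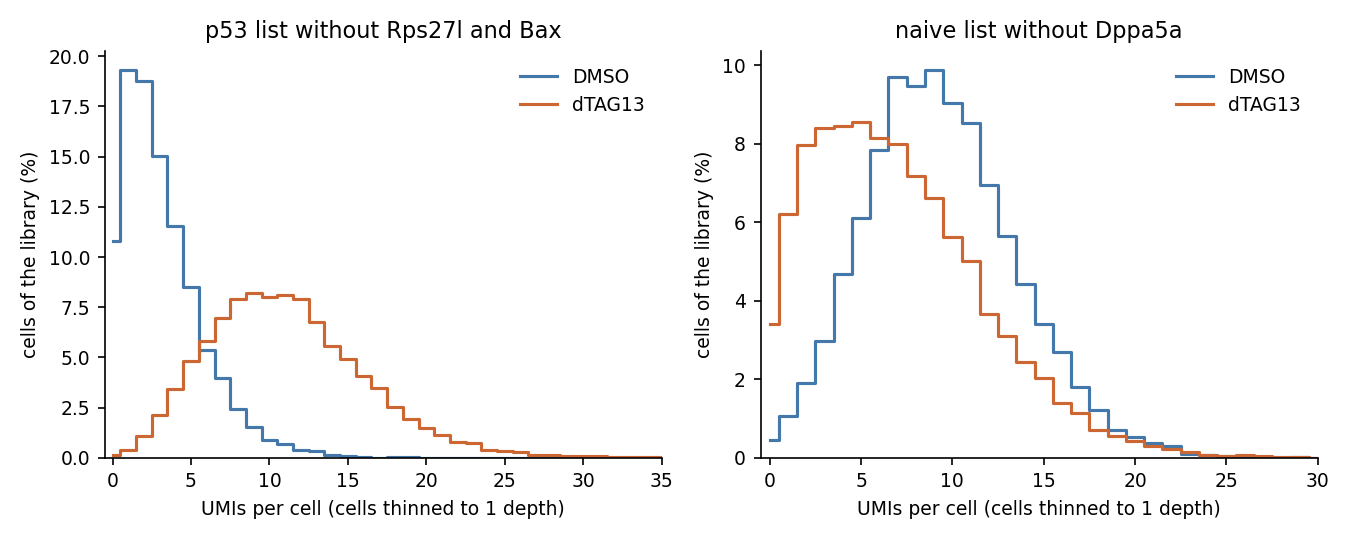
UMIs per cell (x axis, cells thinned to 3900 UMIs) against the share of each library's cells (y axis, percent), for the p53 target list without Rps27l and Bax (left) and the naive pluripotency list without Dppa5a (right), in the DMSO and dTAG13 libraries. The p53 list has medians of 3 UMIs with DMSO and 11 with dTAG13, and the naive list has medians of 9 and 6.

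The genes with the highest ratios were not confined to the p53 list. Nectin4, a cell adhesion gene, was at 1.54 CPM with DMSO and 35.2 CPM with dTAG13, a ratio of 22.9 (19.7 to 26.8). The stress-induced transcription factor gene Atf3 was at 1.51 and 23.4 CPM, the neurogenic factor gene Neurod1 at 3.49 and 44.5 CPM, and Ddit4, an inhibitor of mTORC1 signalling, at 6.29 and 73.4 CPM. The hormone gene Sct, the glutathione peroxidase gene Gpx3, Nudt18 and the protease inhibitor gene Serpine2 followed, with ratios between 8.28 and 10.0. Zfp365, Synm and Bbs7 had ratios of 7.58, 7.31 and 7.06. These genes and Mdm2, Btg2 and Plk2 are among the 15 highest of 4792 genes that met the naming limits.

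At the other end, Sfrp1, a secreted Wnt antagonist, was at 45.1 CPM with DMSO and 9.50 CPM with dTAG13, a ratio of 0.210 (0.196 to 0.226). The X-linked homeobox genes Rhox9, Rhox6 and Rhox5 had ratios of 0.236, 0.248 and 0.338, and the Ras-family genes Mras and Eras had ratios of 0.241 and 0.390. Tcf15, a transcription factor gene of cells leaving the naive state, was at 96.5 and 34.7 CPM. Serpinb6c, Cpne5, Plac8, Nid1, Mov10, Khdc3 and Nfib had ratios between 0.255 and 0.396, and Tcl1, a naive marker, is described with its list.

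Naive pluripotency genes, which are active in cultured embryonic stem cells and are shut down as differentiation begins, were lower in the dTAG13 library. Tcl1, a cofactor of Akt, was at 45.4 CPM with DMSO and 12.8 CPM with dTAG13, a ratio of 0.281 (0.263 to 0.299). The transcription factor genes Nr0b1 and Tfcp2l1 had ratios of 0.609 and 0.616, and Zfp57, which guards imprints, had a ratio of 0.643. Of 17 measured members, 5 were at least 1.5-fold lower, 0 were at least 1.5-fold higher and 2 had a ratio above 1. The median log2 ratio was -0.43 (counting interval -0.47 to -0.39), at percentile 0 of random lists. It was -0.48 in cells called G2 and M but -0.09 in cells called S and -0.09 in cells called G1, where it lay inside the central 95% of random lists. It also lay inside that range within most clusters with at least 50 cells of each library, as given with them below. Cluster 9, with 1849 dTAG13 and 42 DMSO cells, was not among these. Its summed naive CPM, 6207, was the lowest of the 5 clusters that held most dTAG13 cells. That sum includes Dppa5a, which holds most naive UMIs, so it says little of the other members.

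The genes shared by naive and later pluripotent cells had a median log2 ratio of 0.01 over 9 measured members. Pou5f1 was at 612 and 516 CPM, Sox2 at 291 and 334 CPM, L1td1 at 539 and 385 CPM and Zfp281 at 26.2 and 28.7 CPM, and Nanog, a member of the naive list, was at 86.2 and 72.6 CPM. The formative list, of the state that follows the naive one, had a median of 0.02 over 8 members, and one of 0.36 with no minimum CPM, with Sox4 at 11.2 and 17.0 CPM, Zic5 at 13.0 and 9.37 CPM, and the DNA methyltransferase genes Dnmt3b and Dnmt3a at ratios of 0.935 and 0.945. Per thinned cell, naive list UMIs had a median of 37 with DMSO and 33 with dTAG13, and formative list UMIs a median of 0 in both. More formative than naive UMIs were found in 1 of 16123 DMSO cells (0.00620%, interval 0.000157 to 0.0346) and 6 of 10815 dTAG13 cells (0.0555%, 0.0204 to 0.121), or 1 of 17878 and 6 of 11588 cells without thinning. Dppa5a holds most naive UMIs, and without it these shares were 0.571% and 2.85%. Mean formative UMIs per thinned cell were 0.387 with DMSO and 0.421 with dTAG13. Without Dppa5a, 75 DMSO cells (0.465%) and 369 dTAG13 cells (3.41%) held 0 naive UMIs. In such cells 1 formative UMI is enough to be counted, so these shares can rise from fewer naive UMIs alone.

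Stress-response lists differed in size and did not all leave the random range. The immediate-early list, of genes switched on within minutes by growth signals or tissue dissociation, had a median log2 ratio of 1.02, with 8 of 12 members at least 1.5-fold higher; Jun was at 15.2 and 74.9 CPM and Jund at 180 and 386 CPM. The integrated stress response list had a median of 0.47, with 7 of 16 members at least 1.5-fold higher and 3 at least 1.5-fold lower; Ddit3 was at 3.73 and 18.4 CPM and Cebpb at 6.03 and 17.3 CPM. Both lay above the central 95% of random lists. Each shares 1 member with the p53 list, and without it the integrated stress response median was 0.36 (percentile 98.8). This leaves out only genes on the fixed p53 list, so other p53 targets may remain in both lists. The full integrated stress response list had a median of 0.14 when at least 20 CPM was required and 0.26 with no minimum. Heat shock genes had a median of -0.21 (percentile 2.70, inside the central 95%), or -0.05 with no minimum CPM, with Hsph1 and Dnaja1 at ratios of 0.673 and 0.684, Hspd1 at 0.785 and Dnajb1 at 1.36. Of the apoptosis list, 6 of 15 members were at least 1.5-fold higher, with the BH3-only genes Pmaip1 and Bbc3 at ratios of 5.49 and 2.68 and the apoptosome gene Apaf1 at 3.63. The apoptosis median was 0.26 (percentile 96.3), and 0.24 without its 3 p53 members. Lysosomal and autophagy genes had a median of 0.22 (percentile 86.0), or 0.54 at 20 CPM or more, with Ctsd, Sqstm1 and Ctsb at ratios of 2.60, 1.70 and 1.45 and Lamp1 at 229 and 344 CPM.

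Ribosome biogenesis transcripts, which encode the factors that process and assemble ribosomes, had a median log2 ratio of -0.04 over 36 members (percentile 37.9), though it lay above the random range within several clusters described below. Utp20 was at 84.4 and 153 CPM and Nob1 at 121 and 156 CPM, while Nolc1 was at 458 and 325 CPM and Rrp1b at 151 and 112 CPM. Ribosomal protein genes had a median of 0.03 over 82 members, which was -0.04 after scaling by the median of ratios; Rpl22l1 was at 1307 and 487 CPM, Rpl3 at 2168 and 1584 CPM, Rps23rg1 at 7.20 and 10.6 CPM, and Rps27l, also a p53 target, at 1543 and 2275 CPM.

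Metabolic lists were slightly lower in the dTAG13 library. Mitochondrial genome transcripts had a median of -0.28 (percentile 0.445), with ratios of 0.754 for mt-Atp6, 0.756 for mt-Nd1 and 0.807 for both mt-Cytb and mt-Co3. The nuclear respiratory chain list had a median of -0.16 over 91 members (percentile 2.15), with Atp5g1 at 0.616, Cox7a1 at 0.591, Cox6b2 at 1.73 and Ndufb6 at 1.52. Glycolysis and hypoxia genes had a median of -0.19 (percentile 0.825), with Pfkp at a ratio of 0.426, Aldoa at 371 and 259.7 CPM, and Pdk1 and Tpi1 at ratios of 0.731 and 0.761. Cholesterol synthesis genes had a median of -0.15 (percentile 0.480), with Fdps, Idi1 and Cyp51 at ratios of 0.709, 0.755 and 0.782.

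Imprinted genes, expressed from a single parental copy, had a median log2 ratio of 0.85 (percentile 100). Of 13 measured members 8 were at least 1.5-fold higher and 0 lower by as much: Peg10 was at 7.69 and 23.0 CPM, Meg3 at 73.6 and 169 CPM, Rian at 21.9 and 44.4 CPM and Cdkn1c at 21.8 and 40.3 CPM. The median was 0.45 in cells called G1, inside the central 95% of random lists, 0.56 in cells called S and 0.55 with no minimum CPM. DNA methylation enzymes had a median of -0.14 (percentile 8.09), with Uhrf1 at 0.595, Apobec3 at 0.609, Tet2 at 0.758 and Dnmt3l at 1.62, and polycomb genes a median of 0.03 (percentile 52.9), with Epop at 0.452, Pcgf6 at 0.815, Jarid2 at 0.821 and Aebp2 at 1.58.

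Among signalling lists, BMP targets had a median of 0.39 (percentile 97.6), with Id3 at 75.3 and 133 CPM, Id1 at 300 and 485 CPM, Id2 at 122 and 181 CPM and the ligand gene Bmp4 at 13.1 and 3.62 CPM. Wnt targets had a median of -0.45 over 5 members (percentile 2.57), with Tcf7 at a ratio of 1.74 and Ccnd1 at 0.788. Its direction depends on the settings: the median was 0.82 with no minimum CPM, 0.23 with at least 20 CPM and -1.10 in cells with at least 1000 genes. Nodal targets had a median of -0.13 over 8 members (percentile 7.48), with Nodal at 37.3 and 86.3 CPM and Lefty2 at 86.4 and 44.7 CPM, and the median was 0.14 with no minimum CPM. FGF-ERK targets had a median of 0.11 (percentile 29.2), or 1.52 at 20 CPM or more, with Phlda1 at 5.75 and 38.2 CPM, Etv5 at a ratio of 1.23, Egr1 at 0.854 and Spry2 at 1.08.

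Lineage markers were mostly low. Of the trophoblast list, 6 of 14 members were measured: the keratin genes Krt8 and Krt18 had ratios of 2.64 and 2.62, while Rhox9 and Rhox6 were the lower members given above. The list's median was 1.39 with 4 members at least 1.5-fold higher and 2 lower by as much, and -0.31 when at least 20 CPM was required. Epithelial genes had a median of 0.38 (percentile 99.3), with Krt8 and Krt18 shared with the trophoblast list, Cldn6 at a ratio of 2.23 and Cdh1 at 84.8 and 127 CPM. Germ cell markers had a median of -0.02, with Tfap2c at 39.5 and 94.8 CPM, Prdm1 at 16.7 and 9.02 CPM, Stk31 at a ratio of 0.622 and Nanos3 at 0.663. No primitive streak marker reached 5 CPM in either library. The only measured nascent mesoderm marker was Etv2, at 10.8 and 5.28 CPM, and the only measured definitive endoderm marker was Trh, at 98.1 and 71.7 CPM. Extraembryonic endoderm markers had a median of 0.54 over 3 members (percentile 93.4), with Lamb1 at 21.6 and 31.7 CPM and Sparc at 158 and 230 CPM. Neural ectoderm had 2 measured markers, Nes at 5.64 and 21.0 CPM and Tubb3 at 53.4 and 38.0 CPM, with a median of 0.70. Fibroblast feeder markers had a median of -0.09 over 2 members, with Tagln at 27.6 and 85.7 CPM, and mesenchymal genes a median of -0.21 over 2, with Fn1 at 90.1 and 63.9 CPM and Vim at 69.7 and 73.6 CPM. Of the 2-cell-like markers only Zfp750 reached 5 CPM, at 4.76 and 15.7 CPM.

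Cell cycle transcripts were lower for S phase. Gmnn and Cdc6, regulators of replication origins, had ratios of 0.537 (0.526 to 0.548) and 0.553 (0.529 to 0.578), the repressor gene E2f8 had a ratio of 0.567 and Uhrf1 one of 0.595. Of 42 members 8 were at least 1.5-fold lower and 1 was at least 1.5-fold higher, with a median log2 ratio of -0.29 (counting interval -0.31 to -0.27), at percentile 0 of random lists. In cells called S the median was -0.03, inside the central 95%. The G2 and M list had a median of 0.09 over 51 members, just above the central 95% of random lists, with Psrc1, Gtse1 and Ckap2, also p53 list members, at ratios of 2.43, 2.17 and 1.94, and Hmmr at 1.70. Without these 3 shared members its median was 0.08 (percentile 97), inside the central 95%, and it was -0.66 in cells called G1 and -0.19 in cells called S. In thinned cells, G1 was called for 0.608% (0.494 to 0.740) of DMSO cells and 13.2% (12.6 to 13.9) of dTAG13 cells, S for 23.6% (22.9 to 24.2) and 14.6% (14.0 to 15.3), and G2 and M for 75.8% (75.1 to 76.5) and 72.2% (71.3 to 73.0). Without thinning, G1 calls were 1.17% and 16.4%. The phase lists read free RNA as well as the cells' own, which was left open, and the calls alone do not measure cycling.

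The joint clustering mostly separated the libraries. Across 17 clusters, 6 clusters (Sfrp1, Fgf17, Nanos3, Septin1, Rhox9 and Ly6a lead them) held 16170 DMSO cells (90.4%) and 627 dTAG13 cells (5.41%, 5.01 to 5.84), and 5 clusters (led by H2ac18, Krt19, Neurod1, Atf3 and 2810013P06Rik) held 650 (3.64%, 3.37 to 3.92) and 10634 (91.8%, 91.3 to 92.3). With 1 library per group, such clusters may be the library rather than a cell type, and their sizes follow from the genes that differ between the libraries. Only cluster 10, led by 2810013P06Rik, Btg2, Sdc4, Serpine2 and 9230114K14Rik, had at least 200 cells from each library (208 DMSO and 1173 dTAG13 cells). Within it the p53 list had a median log2 ratio of 0.27 (counting interval 0.14 to 0.39), with 6 of 31 members at least 1.5-fold higher and 1 at least 1.5-fold lower. In the other 10 clusters with at least 50 cells of each library the p53 median ran from 0.29 to 1.15. Cluster 10 thus had the lowest, but the 0.29 of cluster 5 lies inside cluster 10's counting interval. Btg2 and Plk2, members of the list, are among the 10 leading genes of cluster 10. Its DMSO cells had Mdm2 at 173 CPM, against 45.3 CPM in the whole DMSO library. The low p53 ratio there follows in part from how its cells were grouped. Ribosome biogenesis genes had a median of 0.17 in cluster 10, with 29 of 36 members higher in dTAG13 cells, and also lay above the central 95% of random lists in clusters 1, 5, 6, 7 and 11. The immediate-early list had a median of 0.49 in cluster 10 and the S phase list one of -0.17, both outside the central 95% of random lists. S phase medians were also below that range in clusters 5, 6 and 7, inside it in clusters 1, 2, 3, 4, 8 and 13, and above it in cluster 11 (0.23). Immediate-early medians were above 0 in all 11 clusters, and above the range in clusters 2, 4, 6, 8 and 10. The naive list, lower between the whole libraries, had a median of -0.03 (percentile 31.2) in cluster 10. In clusters 1 (with 89 dTAG13 cells), 2, 3, 4, 5 and 7 it also lay inside the central 95%. It was -0.41 in cluster 6, -0.17 in cluster 8, -0.21 in cluster 11 and -0.53 in cluster 13. Cluster 9, with 1849 dTAG13 and 42 DMSO cells, was not compared. Its summed naive CPM of 6207 was the lowest of the 5 clusters made mostly of dTAG13 cells, where the others had 8622 to 9412. These sums include Dppa5a, which holds most naive UMIs, so they say little of the other members. Clusters were formed from gene levels, so comparing within them can remove part of a naive difference. Cluster 10's highest ratios were those of Cpox (3.04), H1f0 (2.94), Ddit4 (2.72), Atxn3 (2.68) and Sesn3 (2.67), on as few as 9 DMSO UMIs, and the lowest those of Rhox5 (0.295), Sfrp1 (0.345), Tcf15 (0.370), Ptch1 (0.389) and Klhl13 (0.392).

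**Figure D3:**
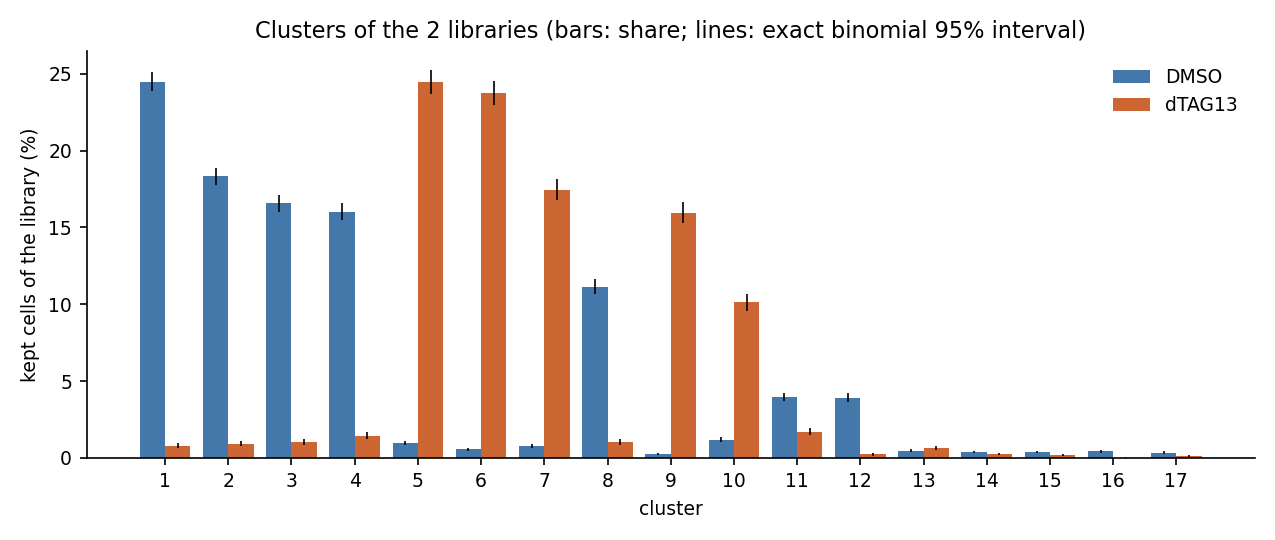
Share of each library's kept cells (y axis, percent) in each of 17 clusters (x axis, cluster number) for the DMSO and dTAG13 libraries, with exact 95% binomial intervals as lines. Clusters 1, 2, 3, 4, 8 and 12 together hold 90.4% of DMSO cells, and clusters 5, 6, 7, 9 and 10 hold 91.8% of dTAG13 cells.

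Named cell types were rare. A 2-cell-like cluster, of cells that briefly express genes of the early cleavage embryo, was led by Eif1ad and Zscan4 genes. It held 85 DMSO cells (0.475%, 0.380 to 0.588) and 71 dTAG13 cells (0.613%, 0.479 to 0.772). When the genes that define it were left out of the clustering, a choice made after the data were seen, it held 77 (0.431%, 0.340 to 0.538) and 67 (0.578%, 0.448 to 0.734), whose intervals overlap. A trophoblast-like cluster led by Plac1, Krt18, Hand1, Magea9 and Pmp22 held 58 DMSO cells (0.324%, 0.246 to 0.419) and 12 dTAG13 cells (0.104%, 0.0535 to 0.181). No cluster took this name when its defining genes were left out, so its sizes are not compared. The limit on pluripotency genes set after the data were seen kept a keratin cluster led by Krt19 from this name; it held 0.543% (0.440 to 0.661) of DMSO cells and 23.8% (23.0 to 24.6) of dTAG13 cells.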

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

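Added after the data were seen: 8% doublet-score removal, single phases, p53 members left out, Dppa5a left out, thinning before summing and clustering without defining genes. No paired analysis was possible because each group is 1 library. Under the alternatives run for each, the p53 list stayed between 1.15 and 1.59, the naive list between -0.50 and -0.09, S phase between -0.63 and -0.03, immediate-early between 0.94 and 1.11 and imprinted genes between 0.45 and 0.85. Of 712 settings of the 89 named genes at 1.5-fold or more, 0 changed direction, and the largest move was 0.26 on the log2 scale. A turn was unlikely from the start. Median of ratios scaling shifts every gene by 0.07, the cell filters mostly keep the same cells, and single phases and clusters were not among these settings. As no doublet was called, omitting doublet removal changed 0 results.

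The alternative of median of ratios scaling, which lowers each log2 ratio by a like amount by construction, gave -0.41 for Tex10, -0.50 for the naive list, 1.37 for p53 targets, 0.94 for immediate-early genes, -0.36 for S phase, 0.011 for G2 and M, and turned ribosomal proteins to -0.045. Thinning before summing gave -0.27 for Tex10, -0.36 for naive and 0.052 for G2 and M. Weighting cells equally gave 1.11 for immediate-early, -0.34 for S phase and 0.052 for G2 and M. With no minimum CPM the values were -0.48 for naive, 0.96 for immediate-early and 0.55 for imprinted genes, and with at least 20 CPM immediate-early genes had 1.10.

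In cells called G1, 98 with DMSO from several clusters and 1428 with dTAG13 of which 1365 lay in the keratin cluster, the medians were 1.59 for p53 targets, -0.094 for naive, 1.11 for immediate-early, 0.45 for imprinted, -0.63 for S phase and -0.66 for G2 and M. In cells called S they were 1.15, -0.094, 0.96, 0.56, -0.030 and -0.19, and in cells called G2 and M naive, imprinted, S phase and G2 and M had -0.48, 0.74, -0.19 and 0.20. Phases are called from the S and G2 and M lists, so these lists move by construction; for the others the cause was not tested.

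Lists with few members turned with the minimum: the trophoblast list became -0.31 at 20 CPM, and nascent mesoderm, with 1 measured member, became 0.53 with no minimum and 0.30 without the 8% highest doublet scores, as other members entered. As members entered or left, with no minimum and at 20 CPM, Wnt targets became 0.82 and 0.23, fibroblast feeder markers 0.28 and 1.64, integrated stress response genes 0.26 and 0.14, FGF-ERK targets 0.28 and 1.52, BMP targets 0.21 and 0.63 and Nodal targets 0.14 and -0.38. With no minimum, mesenchymal genes became 0.38, neural ectoderm 0.16 and heat shock -0.05. Wnt targets had -1.10 in cells with at least 1000 genes. At 20 CPM lysosomal genes had 0.54, DNA methylation enzymes -0.22, heat shock -0.12 and cholesterol synthesis -0.09, and with no minimum 2-cell-like markers had 1.12. The formative, shared pluripotency, germ cell, polycomb and ribosome biogenesis lists took either sign, and the formative list had 0.36 with no minimum. The DMSO share of 2-cell-like cells was 0.366% after thinning. The DMSO share of trophoblast-like cells was 0.492% at resolution 2, 0.470% without cell cycle genes and 0.510% without the 8% highest doublet scores, and no such cluster formed without its defining genes; the cause was not tested. Without Dppa5a, which holds most naive UMIs, 0.571% of DMSO and 2.85% of dTAG13 cells had more formative than naive UMIs. As given above, these shares can rise from fewer naive UMIs alone. Unthinned phase calls were 1.17% (G1) and 74.7% (G2 and M) for DMSO, and 16.4% (G1), 13.9% (S) and 69.7% (G2 and M) for dTAG13. Cell number limits the trophoblast-like share, set by 12 dTAG13 cells (14 after thinning). Depth limits shares of cells with a UMI: for Tex10 with DMSO, 39.5% unthinned and 26.8% thinned.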

Other observations

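Of the tests here, those on handling stress, on carried-over DMSO cells, on free RNA, on trophoblast identity, on few cell cycle UMIs per cell, on rho within clusters, and the histone and Rhox sets were chosen after the results were seen. Replication-dependent histone genes, picked by symbol after they led a cluster of the dTAG13 library, were higher in that library in 34 of 34 measured genes, with a median log2 ratio of 0.41 (percentile 99.97 of random lists), though only 12 were at least 1.5-fold higher. Levels of its own members prompted the set, so this percentile adds no separate support. The counting intervals of H4c9, H2ac10 and H2bc3 include a ratio of 1. H4c9 (log2 ratio 0.02) lies below the 0.07 shift of median of ratios scaling. H1f4 was at 180 and 354 CPM, H4c4 at 53.4 and 102 CPM and H2ac18 at 4.68 and 9.65 CPM in the DMSO and dTAG13 libraries. Most of these mRNAs lack a poly(A) tail, so a 3′ poly(A) kit counts an unknown part of them. The 4 measured Rhox genes had a median of -1.79. Xist, chosen after its value was seen, was at 3.25 and 13.1 CPM in this male line.

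Within the 2-cell-like cluster, Zscan4 genes were higher in the dTAG13 cells. Zscan4d was at 252 CPM (211 to 298) in 85 DMSO cells and 546 CPM (483 to 616) in 71 dTAG13 cells, and Zscan4e at 346 and 785 CPM, though reads shared between near-identical copies make these and the histone and Rhox values uncertain. Summed over the whole libraries, the Zscan4 genes of the list had 3.71 CPM (3.37 to 4.08) and 9.67 CPM (9.05 to 10.3). A cluster of the DMSO library led by Chac1, Nupr1, Derl3, Herpud1 and Ddit3, genes of the unfolded protein and integrated stress responses, held 76 DMSO cells and 1 dTAG13 cell. Cluster 11 stayed unnamed and held 706 DMSO cells (3.95%, 3.67 to 4.24) and 196 dTAG13 cells (1.69%, 1.46 to 1.94). By genes chosen after their values were seen, it had Dnmt3b at 101 CPM against 29.1 CPM in other cells and Fgf8 at 18.2 against 0.692 CPM. Its dTAG13 cells also had more Mdm2 than its DMSO cells (142 and 51.0 CPM).

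The p53 target difference was weighed against depth, handling stress and the library. A difference in depth was predicted to leave a median under 0.3 once cells were thinned to the same depth, and the median was then 1.47. The ratio is of CPM, and random thinning keeps each gene's expected share, so the median had to stay near 1.44. This result thus decides nothing about depth. At 3900 UMIs per cell the list still had medians of 11 UMIs in DMSO cells and 22 in dTAG13 cells. Stress from dissociation would raise heat shock and immediate-early genes together; the heat shock median was -0.21 while the immediate-early median was 1.02, so handling stays open. With 1 library per group, an effect of that library, or of dTAG13 itself on cells, cannot be told apart from loss of the tagged protein. Loss of the tagged protein stays open and untested, and a second pair of libraries and dTAG13 on untagged cells would be needed.

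A set of 627 dTAG13 cells lay in the 6 clusters made mostly of DMSO cells, and DMSO cells or barcodes carried into the dTAG13 library could put them there. If these had taken up no RNA there, they would match the DMSO cells of those clusters in p53 targets, yet their list median was 0.76 above those cells on the log2 scale, which argues against such unaltered cells as the whole source. Carried-over cells that took up free RNA of the dTAG13 library cannot be told apart from a partial response: Mdm2, at 109 against 39.5 CPM, would need a free RNA share of 21.4% (18.7 to 24.4), Cdkn1a 36.1% (30.5 to 42.1) and Ccng1 41.6% (35.5 to 48.0), shares that differ from each other and exceed the bound of 14.8% from Zscan4, but that bound rests on 2 UMIs and, like these shares, on the assumption that free RNA has the make-up of the whole library. Barcodes shared with the DMSO library were 0.478% of them and 0.547% of the other dTAG13 cells. Barcodes that hold more than 1 cell also stay open, though the 627 cells had a median of 7378 UMIs. The dTAG13 cells of the 5 clusters made mostly of dTAG13 cells had a median of 7054. In those 5 clusters lay 650 DMSO cells, with Mdm2 at 187 CPM and Cdkn1a at 157 CPM. The DMSO cells of the 6 clusters had 39.5 and 63.1 CPM. Whether the 650 were carried-over dTAG13 cells or DMSO cells with more p53 target transcripts was not tested.

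The keratin cluster of the dTAG13 library held 2755 dTAG13 cells with Krt18 at 103 CPM against 18.0 CPM in the other dTAG13 cells, Cdkn1a at 318 against 214 CPM, and fewer cell cycle transcripts (G2 and M list 4196 against 11820 CPM). Damaged cells would hold more mitochondrial UMIs, yet their median share was 0.862 of that of the other cells, which argues against damage of that kind, though they also had fewer UMIs (median 5169 against 7658). Trophoblast cells would have lost pluripotency transcripts, yet the shared pluripotency list was at 0.903 of its level in the others. The limit that kept this cluster from the trophoblast name used a like measure and was set after the data were seen. The value is thus no separate test of that name. Of 14 trophoblast markers, Hand1, Krt7, Krt8, Krt18 and Ascl2 had at least 10 CPM and 2 times their level in other cells. The rest, Plac1 and Rhox6 among them, did not. Whether Cdkn1a and few cell cycle transcripts go together cell by cell is not decided, with a Spearman rho of -0.079 across thinned dTAG13 cells. Whether these cells cycle less stays open, as transcripts do not measure it. Over all thinned dTAG13 cells, not the keratin cluster alone, 23.3% (22.5 to 24.1) had fewer than 40 cell cycle UMIs. That limit is the 5th percentile of DMSO cells, so the DMSO share of 4.39% follows from the choice. In the DMSO and dTAG13 libraries 732 and 467 cells lay within 2 UMIs of it. The share within the keratin cluster was not taken.

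A hypothesis is that the naive programme is lower in the dTAG13 cells with more p53 target UMIs. Across 10815 thinned dTAG13 cells the Spearman rho of the p53 and naive lists was -0.230, and across DMSO cells it was -0.076. The p53 list here includes Rps27l and Bax, and the naive list leaves out Dppa5a. Cells are not independent replicates. The 2878 dTAG13 cells with the fewest p53 UMIs had a mean of 8.25 naive UMIs without Dppa5a, and the 2972 with the most had 5.84. Within the 5 clusters of at least 500 thinned dTAG13 cells, rho was -0.225 in cluster 6 and -0.198 in cluster 10. It was -0.099 in cluster 7, -0.077 in cluster 5 and -0.072 in cluster 9. The naive list differed little between the libraries within most clusters compared (median log2 ratio -0.03 in cluster 10). Cluster 9, with 1849 dTAG13 and 42 DMSO cells, was not compared. Among the 5 clusters it had the lowest summed naive CPM (6207) and the highest summed p53 list CPM (6677). That naive sum includes Dppa5a, which holds most naive UMIs, so it does not bear on the rho and means without Dppa5a. In clusters 5, 7 and 9 rho was weaker than the pooled rho, so differences between clusters may hold part of it and of the means above. The relation may come from another property of the cells, such as cell cycle position, which was not tested.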
